A study of Mus musculus with 8 samples.

How the data were processed

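RNA from mouse uterine epithelium was sequenced as 8 libraries, 3 from control mice and 5 from mice in which floxed Smad2 and Smad3 were deleted by a Cre recombinase expressed from the progesterone receptor locus (Pgr-cre). These are called cKO below. Per the labels' protocols, all lines shared a mixed C57BL/6/129S6/SvEv background, the floxed segments were exons 9 and 10 of Smad2 and exons 2 and 3 of Smad3, and cDNA was primed with both random and poly-dT primers before library construction and sequencing on a HiSeq 2500. The age of the mice, the stage of the cycle and the way the epithelium was isolated are not given in the sources used here. The group of each library was taken from its genotype label, and the replicate numbers only name the libraries. The labels give no pairing of control and cKO libraries and no batch. The titles of cKO 1 and cKO 2 belong to another number series than those of the other 6 libraries, called the main title series below, and this was carried as a possible batch.

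Per the submitters' processing notes, bcl2fastq 1.8.3, TopHat, Cufflinks and the mm10 genome were used; the versions of TopHat and Cufflinks, the annotation release and the use of strand are not given in the sources used here. The deposited values are FPKM, fragment numbers scaled by transcript length and by the mapped fragments of the library, computed by the authors in each library separately, with a 95% interval and a status for each of 34535 RefSeq transcripts, per the file headers. The deposited coverage signal of each transcript, per the file headers the mean depth over it, was used only to look at library depth. No read counts were used. The number of mapped fragments was estimated from the width of the deposited FPKM intervals of genes with 1 transcript, and lay between 44.2 and 55.6 M per library. Fragment numbers recovered in this way were not whole for most low genes (45.5% to 48.1% lay within 0.02 of a whole number), so no count test was run.

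Transcript FPKM was summed per gene symbol, giving 24346 symbols, and 34169 transcripts were matched by accession to a current symbol of the GRCm38.p6 annotation. A total of 15 genes whose status was not OK in at least 1 library were left out. They include lactotransferrin (Ltf), which Cufflinks set to 0 because of excess data in 6 libraries, and complement C3, set to 0 in 3 libraries. Coordinates are those of the deposited tables on mm10, written 1-based. Libraries were put on 1 scale by the median ratio to the geometric mean over genes with FPKM of at least 1 in every library, which gave factors between 0.924 and 1.06. Genes with a scaled FPKM of at least 1 in at least 3 libraries were tested, 11315 in all.

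Differences between cKO and control were tested with limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1), with a variance trend, two-sided, and Benjamini-Hochberg adjustment; genes with an adjusted p below 0.05 were called. All log2 fold changes are cKO minus control on this scale, which understates the change of genes with low values, and carry the standard error of the limma fit. Group values are mean scaled FPKM ± SD. Smad2, Smad3 and the mean log2 level of each marker list were also tested by exact permutation over the 56 splits of 8 libraries into 3 and 5, two-sided, where the smallest possible p is 0.0179. The same test of the mitosis and DNA replication lists was chosen after the results were seen, and is not adjusted. A total of 33 gene lists (pathways, and markers of the cell types that the preparation could hold) were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 32 lists with at least 3 tested members. Camera was repeated with an estimated correlation, and fry was run beside it. The list of ovary and corpus luteum markers had fewer than 3 tested members and has no test.

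The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Smad2, Smad3 and Pgr; the 12 largest rises and 12 largest falls among called genes with no overlap between groups and a mean scaled FPKM of at least 5, passing over symbols that are only model names, small RNAs and pseudogenes; up to 4 called members of each list by adjusted p, or the 2 most abundant members of a pathway list with none; and the 4 most abundant called genes in each direction. Genes named outside the rule are said to be so. The alternatives were FPKM without scaling, TPM, quantile normalization, a pseudocount of 0.1, no filter and a filter at FPKM 5, keeping genes with a status other than OK, other variance models, array weights, leaving out each library or both cKO libraries of the other title series, and the title series or the stromal and muscle marker level as a term.

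The fit was tested on simulated data made from the real means and spreads of the cKO against control comparison, with 200 changed genes per size. The changed genes were drawn from those with a control level of at least 5 scaled FPKM, so the shares recovered do not cover lower genes. Noise was drawn separately for each gene, so shifts shared by many genes were not simulated. Log2 changes of 0.5, 1 and 2 were recovered in 6.5%, 86.0% and 97.0% of genes, among 11052, 11046 and 11052 tested genes, with 2, 4 and 12 false calls, and 0 genes were called with no change. With 200 changed genes the fit therefore detected few changes of 0.5. The real comparison called 1613 genes, which makes its adjusted threshold less strict, so the 6.5% need not hold there. Reads from near-identical copies, and from overlapping genes where strand was not used, can be divided between genes by Cufflinks, and values of such genes are uncertain. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.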

Results

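The comparison asks how gene expression in the uterine epithelium differs when SMAD2 and SMAD3, the intracellular transducers of TGF-beta and activin signals, are deleted in cells that express the progesterone receptor. The data are transcript FPKM tables of 3 control and 5 Smad2/3 cKO libraries. Estimated depth was 52.5, 53.9 and 55.6 M mapped fragments in controls 1 to 3, and 55.2, 52.1, 44.2, 52.9 and 49.4 M in cKO 1 to 5. The 10 most abundant genes took 15.5% to 20.04% of all FPKM. The most abundant gene was Lcn2 in the 3 control libraries, Prap1 in 4 cKO libraries and Sprr2f in cKO 4. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these libraries, which may be technical in part.

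Of the targeted genes, Smad2 (chromosome 18, 76241701 to 76311747) was lower in all 5 cKO libraries than in any control, at 3.58 ± 0.378 scaled FPKM (SD, n = 5) against 6.07 ± 0.342 (SD, n = 3). The values were 5.69, 6.35 and 6.18 in controls 1 to 3 and 3.79, 3.03, 4.02, 3.63 and 3.41 in cKO 1 to 5. Its log2 fold change was -0.63 ± 0.10 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00551; exact permutation p = 0.0179, the smallest that 56 splits allow). Smad3 (chromosome 9, 63646767 to 63757994) did not pass, at 30.7 ± 8.97 in cKO against 28.2 ± 3.07 in control, a log2 fold change of 0.08 ± 0.22 (limma adjusted p = 0.837; exact permutation p = 0.768). Without cKO 1 and cKO 2, the libraries of the other title series, the log2 fold changes were -0.59 for Smad2, still past the threshold, and -0.18 for Smad3. Without cKO 1 alone that of Smad3 was -0.045. The Smad3 values were 27.4, 31.5 and 25.6 in controls 1 to 3 and 42.6, 36.4, 29.6, 24.0 and 20.6 scaled FPKM in cKO 1 to 5. A gene-level FPKM also counts fragments from the exons outside the deleted segments, and from cells without Cre, so the Smad3 value does not check the labels. Pgr, the gene that carries Cre (chromosome 9, 8899833 to 8968611), was low in both groups, at 1.12 ± 0.381 against 1.38 ± 0.558 (adjusted p = 0.609).

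The 4 Id genes, which encode inhibitors of basic helix-loop-helix transcription factors and are direct BMP targets, were higher in every cKO library than in every control, with Id1 16.6-fold and Id3 27.5-fold higher by group means. Among single genes, Guca2b, Defb1, Clu, Spp1, Chil1 and the chemokine genes Ccl20 and Cxcl10 rose. Pla2g2e, Spink12, Car9, Peg10 and Itgam fell, as did called genes of cholesterol synthesis. In all, 823 genes were higher and 790 lower in cKO among 11315 tested (limma, Benjamini-Hochberg adjusted p below 0.05), of which 293 and 201 changed at least 2-fold. This is 14.3% of tested genes; 3560 genes had an unadjusted p below 0.05. The groups did not overlap for 2783 tested genes, 24.6% against the 3.57% that chance gives, and for 1558 of the 1613 called genes. Without control 2 the counts were 238 higher and 186 lower (157 and 93 at least 2-fold), without control 3 they were 242 and 176 (159 and 94), and without control 1 the lower genes numbered 441. Array weights gave 1793 higher and 1733 lower (444 at least 2-fold higher), and the stromal and muscle level as a term gave 386 and 328. With TPM 12534 genes met the filter, and the median log2 fold change of tested genes was -0.20 in place of -0.0050. TPM gave 512 higher and 1616 lower (433 at least 2-fold lower), so that 24.1% of calls were higher in place of 51.0%. Among the 6 libraries of the main title series alone, 3 control and 3 cKO, 734 genes were higher and 588 lower, and 996 of these calls were also made with all 8 libraries.

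**Figure D1:**
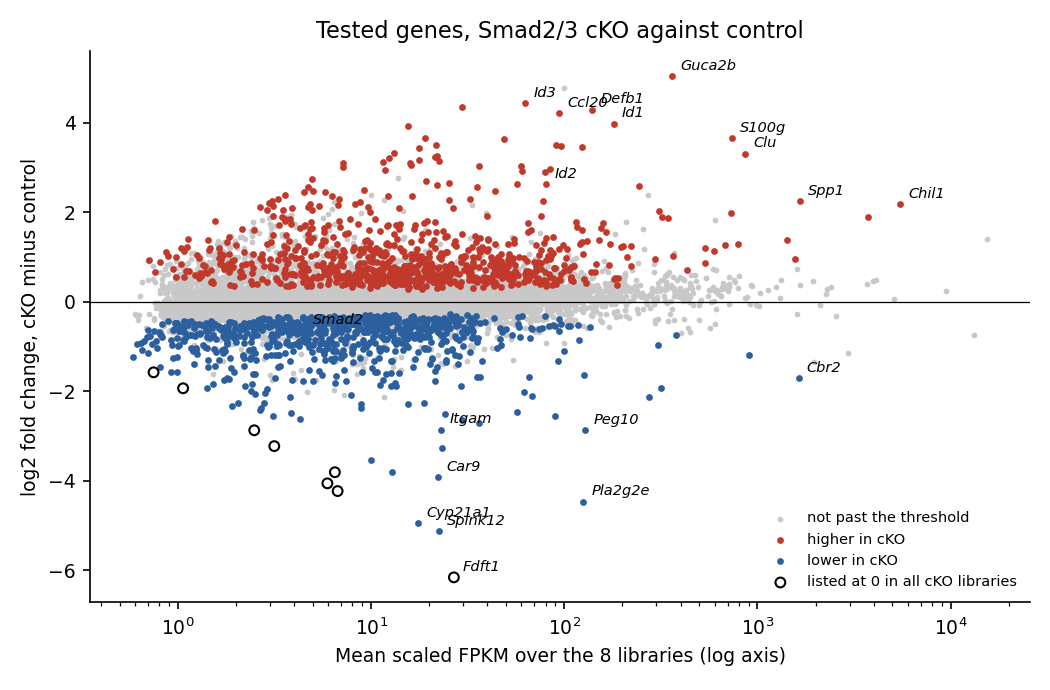
Log2 fold change (cKO minus control, log2(scaled FPKM + 1)) of 11315 tested genes against their mean scaled FPKM over the 8 libraries on a log axis. Red and blue points are the genes called higher and lower in cKO, open circles are 8 genes listed at 0 in all cKO libraries, and Guca2b lies highest at 5.05.

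On the log2(scaled FPKM + 1) scale the largest rise was that of Guca2b, which encodes uroguanylin (chromosome 4, 119656603 to 119658945), from 15.0 ± 6.14 scaled FPKM in control to 569 ± 334 in cKO, a log2 fold change of 5.05 ± 0.48 (adjusted p = 0.000579). This is 37.8-fold by group means, where Abcb1b, with lower values, was 56.4-fold and Awat2 43.9-fold higher. The other 11 genes chosen by size of rise had log2 fold changes between 3.47 and 4.43, and for each all 5 cKO libraries lay above the 3 controls. They were Id3, the drug efflux transporter gene Abcb1b, the beta-defensin gene Defb1, Ccl20, Id1, the wax ester synthase gene Awat2, the calcium-binding protein gene S100g, the pantetheinase gene Vnn3, Orm1, the sulfotransferase gene Sult1d1 and the glutathione peroxidase gene Gpx2. Defb1 went from 10.0 ± 3.41 to 217 ± 79.9, and S100g from 80.4 ± 27.9 to 1132 ± 631. The values of Awat2 and Vnn3 were uneven between cKO libraries, with 1 library at 85.4 and 193 scaled FPKM where the other 4 reached at most 24.3 and 59.1. Among the most abundant called genes, the chitinase-like gene Chil1 rose from 1666 ± 540 to 7747 ± 3022, the osteopontin gene Spp1 from 538 ± 287 to 2325 ± 312 and Ifitm3 from 990 ± 60.6 to 1924 ± 283. The call of Orm1 was lost in 6 of 22 alternatives, among them the main title series alone, that of Ifitm3 in 5, that of Chil1 in 2 and that of Awat2 in 1.

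Of the 12 genes with the largest falls, 8 were measured above 0 in cKO. Spink12, a serine protease inhibitor gene, fell from 58.7 ± 31.6 to 0.58 ± 0.257 scaled FPKM (log2 fold change -5.13 ± 0.29). Cyp21a1, the steroid 21-hydroxylase gene, fell from 46.0 ± 17.5 to 0.453 ± 0.271, though a near-identical pseudogene makes its reads hard to assign. Pla2g2e, a secreted phospholipase gene, fell from 310 ± 46.2 to 14.1 ± 6.07 and the carbonic anhydrase gene Car9 from 55.5 ± 32.8 to 2.30 ± 1.01. The other 4 were Lrmp (-3.80 ± 0.26), Prkcdbp, now named Cavin3 (-3.28 ± 0.24), the imprinted gene Peg10 (-2.87 ± 0.33) and the integrin alpha-M gene Itgam (-2.86 ± 0.23). The 4 remaining genes, Fdft1, Acat3, Il4i1 and Nox1, were listed at 0 in all 5 cKO libraries. Their scaled FPKM in controls 1 to 3 was 85.7, 70.4 and 58.2 for Fdft1, 20.1, 16.9 and 16.6 for Acat3, 14.3, 18.9 and 14.3 for Il4i1, and 3.61, 18.7 and 29.6 for Nox1. No fold change is given for them, since an exact 0 in these tables can be a failed estimate, and each of the 4 overlaps a neighbouring expressed gene. Among the most abundant called genes, the carbonyl reductase gene Cbr2 fell from 2870 ± 325 to 888 ± 210 and the arginase gene Arg1 from 581 ± 268 to 158 ± 73.2. Fcgbp fell from 1364 ± 210 to 630 ± 249 and Scd2 from 501 ± 22.4 to 304 ± 73.6. The calls of Arg1, Fcgbp and Scd2 were lost in 5, 8 and 10 of 22 alternatives.

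**Figure D2:**
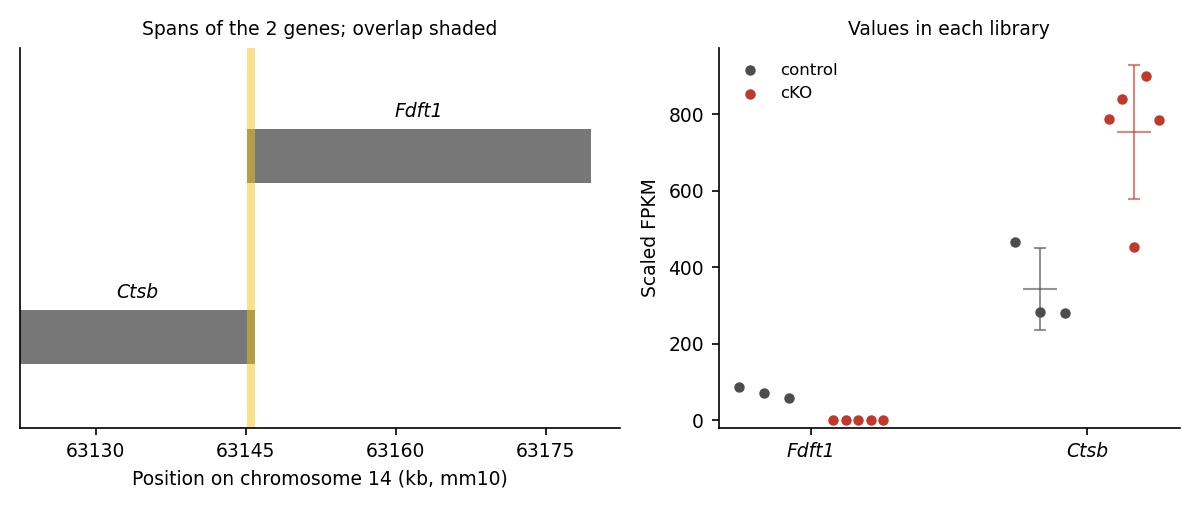
Spans of Fdft1 and Ctsb on chromosome 14 in kb of mm10, with their overlap shaded, and the scaled FPKM of both genes in each of 3 control (grey) and 5 cKO (red) libraries, with mean and SD for Ctsb alone. Fdft1 is listed at 0 in the 5 cKO libraries, where Ctsb lies at 753 on average against 343 in control.

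Among the BMP-response genes, 5 of 10 tested members were higher and 2 lower (6 and 2 adjusted over the list alone), and the list was higher by camera (adjusted p = 0.0017; adjusted p = 0.604 with an estimated correlation). The mean log2 fold change was 1.23, and 1.36 within the main title series. Id1 (chromosome 2, 152736251 to 152737410) rose from 16.7 ± 2.57 to 278 ± 30.4 scaled FPKM, a log2 fold change of 3.98 ± 0.13 (adjusted p = 6.86e-07). Id2 rose by 2.62 ± 0.11, Id3 by 4.43 ± 0.20 and Id4 by 2.48 ± 0.17. The 2 lower members, named after their values were seen, were the Notch and BMP target Hey1 at -1.47 ± 0.34 and the homeobox gene Dlx5 at -0.55 ± 0.09. Of 24 tested TGF-beta response genes, 2 were higher and 3 lower (2 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.619). The lower members were Pmepa1 (from 27.1 ± 1.94 to 10.6 ± 1.87), Skil (-0.46 ± 0.08) and Ski (-0.43 ± 0.12), each a feedback or co-repressor gene of the pathway, while Ctgf, now Ccn2, was higher at 1.29 ± 0.30. Of 22 tested family ligands, receptors and SMADs, 2 were higher, Smad1 and Bambi, and 1 lower, in both counts, and the list did not pass (0.788). The type I receptor gene Acvr1 fell from 12.8 ± 1.09 to 6.72 ± 1.21. The call of Smad1 was lost in 15 of 22 alternatives, that of Ski in 12, Hey1 in 5, Ctgf in 3, Skil in 2 and Dlx5 in 1, and that of Bambi in 9 of 21.

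**Figure D3:**
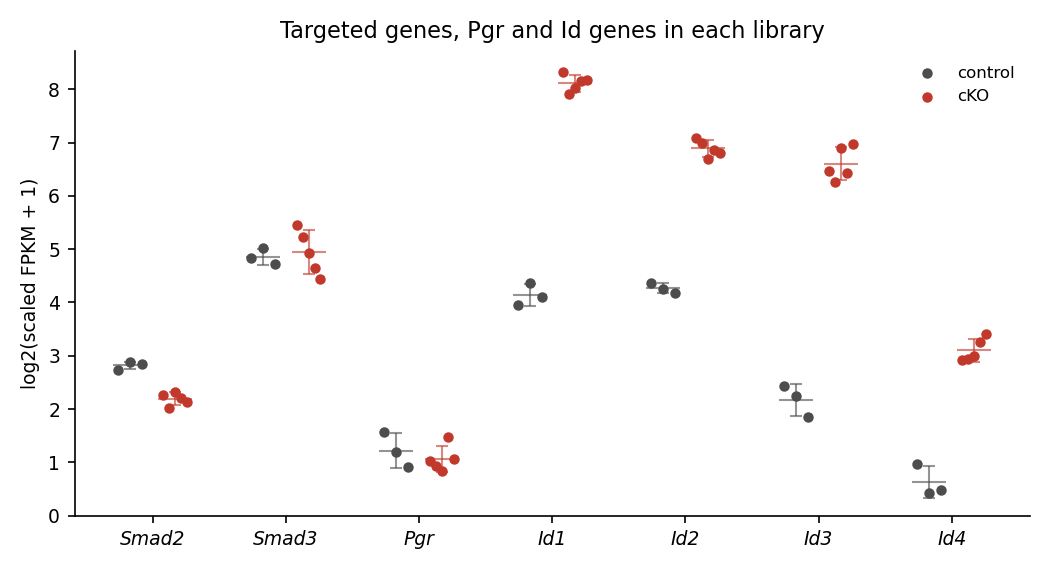
Level (log2(scaled FPKM + 1)) of Smad2, Smad3, Pgr and Id1 to Id4 in each of 3 control (grey) and 5 cKO (red) libraries; points are libraries and bars show the mean and SD. The cKO libraries lie above every control for Id1 to Id4 and below every control for Smad2.

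Inflammatory cytokine, chemokine and mediator genes were higher as a list (camera adjusted p = 0.000676; adjusted p = 0.795 with an estimated correlation), with 8 of 32 tested members higher and 0 lower (10 and 0 adjusted over the list alone). Its mean log2 fold change was 0.74, and 0.53 within the main title series. Cxcl10, a T cell attractant, rose from 4.49 ± 1.09 to 32.4 ± 4.52 scaled FPKM and Ccl20, which attracts CCR6-bearing cells, from 5.57 ± 1.81 to 146 ± 105. Cxcl5, a neutrophil attractant, rose from 114 ± 37.3 to 445 ± 169 and Ccl4 from 7.91 ± 3.70 to 29.4 ± 10.8. The call of Cxcl5 was lost in 4 of 22 alternatives, among them the main title series alone, and that of Ccl4 in 2. Neutrophil markers were higher as a list (adjusted p = 0.00064; adjusted p = 0.795 with an estimated correlation), with 2 of 10 higher and 0 lower, and 7 and 0 adjusted over the list alone. Their mean log2 fold change was 1.54, and 1.51 within the main title series. The called members, Retnlg and Il1r2, went from 1.01 ± 0.485 to 27.8 ± 29.5 and from 7.74 ± 4.76 to 17.9 ± 5.56, and lost their calls in 10 and 12 of 22 alternatives. Interferon-response genes did not pass as a list (0.138), with Rsad2 the 1 higher member of 31 (1 adjusted over the list alone). Complement genes did not pass (0.762), with 2 of 12 higher and 3 lower (3 and 4 adjusted over the list alone). C3 was left out for its status and is not among the 12. The clusterin gene Clu rose from 116 ± 17.1 to 1312 ± 717, and the properdin gene Cfp fell from 38.1 ± 9.28 to 7.02 ± 1.13. Mucin and defence genes missed the threshold (0.0534), with 3 of 12 higher and 0 lower (4 and 0 adjusted over the list alone); Agr2 rose from 1.89 ± 0.648 to 8.40 ± 1.84. Lcn2, the most abundant tested member of the list, named after its values were seen, did not pass at 10748 ± 2933 against 17429 ± 551. Ltf, also a member, was left out for its status. By camera the mucin list passed in 7 of 22 alternatives (lowest adjusted p 0.00132) and the interferon list in 2.

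Cholesterol synthesis genes were lower as a list (camera adjusted p = 2.55e-05; adjusted p = 0.795 with an estimated correlation), with 0 of 23 tested members higher and 7 lower, and 0 and 12 adjusted over the list alone. Mvd, which makes isopentenyl diphosphate, fell from 148 ± 7.01 to 69.6 ± 11.9 scaled FPKM, the sterol reductase gene Tm7sf2 from 44.6 ± 5.17 to 18.9 ± 4.42 and Hsd17b7 from 20.9 ± 1.57 to 10.6 ± 2.17. Fdft1, the squalene synthase gene, is the member listed at 0 in cKO. Without the genes listed at 0 the list's mean log2 fold change was -0.39 in place of -0.64, and it stayed past the threshold (adjusted p = 0.000387; range over its alternatives 7.55e-08 to 0.0106). Within the main title series the mean was -0.57. Without control 1 it was -0.31 and without control 2 it was -0.39, where Fdft1 no longer met the filter. Glycolysis and hypoxia genes did not pass (0.366), with Hk1 and Pfkp higher and Car9 lower among 22, in both counts. The calls of Hk1 and Pfkp were lost in 2 and 3 of 22 alternatives.

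Mitosis genes were higher as a list by camera (adjusted p = 2.57e-06; adjusted p = 0.795 with an estimated correlation), with a mean log2 fold change of 1.595 and of 2.31 within the main title series. However, 0 of 27 tested members were called by limma in either direction, over all genes or adjusted over the list alone, while 20 had an unadjusted p below 0.05. All 27 had a positive log2 fold change. The estimated correlation between members was 0.959, so they moved together across libraries and do not count as 27 separate results. The mean log2 level was 0.75, 0.91 and 0.69 in controls 1 to 3 and 1.91, 0.77, 4.05, 2.95 and 2.22 in cKO 1 to 5, so cKO 2 lay within the control range (exact permutation p = 0.0714). DNA replication genes were also higher by camera (adjusted p = 0.00064; adjusted p = 0.795 with an estimated correlation), with 0 of 28 called in both counts, 9 at an unadjusted p below 0.05 and 25 positive. The estimated correlation between DNA replication members was 0.952. Their mean log2 fold change was 0.73, 1.20 within the main title series and 0.45 without cKO 3. The mean level was 1.97 in cKO 1 and 1.81 in cKO 2, both within the 1.61 to 2.16 of the controls (exact permutation p = 0.179). The most abundant members did not pass, at 21.8 ± 20.9 against 2.81 ± 0.69 for Ube2c and 24.2 ± 7.55 against 17.8 ± 3.83 for Pcna. Ube2c and Birc5, the most abundant of the mitosis list, were each called higher in 4 of 22 alternatives, among them the main title series alone. Among 7 CDK inhibitor genes Cdkn2d was higher, in both counts, by 0.98 ± 0.16, and the list did not pass (0.323).

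Wnt pathway genes were lower as a list (camera adjusted p = 0.0413; adjusted p = 0.795 with an estimated correlation), with 2 of 25 tested members higher and 5 lower, and 5 and 7 adjusted over the list alone. The receptor gene Fzd10 fell from 7.70 ± 1.38 to 1.59 ± 0.513 scaled FPKM, Fzd7 from 12.4 ± 0.475 to 5.26 ± 2.00 and the R-spondin receptor gene Lgr4 from 6.30 ± 0.421 to 2.89 ± 0.636. Porcn, needed for Wnt secretion, rose from 10.7 ± 1.63 to 17.2 ± 2.09. Epithelial-to-mesenchymal transition genes were lower (adjusted p = 0.0413; adjusted p = 0.795 with an estimated correlation), with 0 of 7 higher and 3 lower in both counts: Itga5, Mmp14 and Spock1. Stromal fibroblast markers were lower (adjusted p = 0.0413; adjusted p = 0.795 with an estimated correlation), with Nr2f2 the 1 lower member of 14 in both counts. Within the main title series the mean log2 fold changes of the Wnt, epithelial-to-mesenchymal and stromal lists were -0.35, -0.51 and -0.53, against -0.37, -0.54 and -0.61 with all libraries, and the last 2 did not pass. With the title series as a term none of the 3 passed (0.084, 0.065 and 0.0917). Control 1 stood apart in stromal and muscle markers, with mean log2 levels of 4.03 and 5.01 against 2.95 to 3.07 and 2.74 to 3.28 in the other controls. The epithelial-to-mesenchymal and stromal lists no longer passed without control 1 (0.072 and 0.286), cKO 1 (0.0523 and 0.051), cKO 4 (0.0596 and 0.0789) or cKO 5 (0.0527 and 0.0797), nor the Wnt list without cKO 4 (0.0596) or with TPM (0.224). Without control 1 the mean log2 fold change of the epithelial-to-mesenchymal list was -0.47 and that of the stromal list -0.28. In all, these list calls were lost in 11, 11 and 7 of 22 alternatives. Among members, the calls of Mmp14, Porcn, Nr2f2, Fzd7 and Itga5 were lost in 7, 4, 4, 3 and 3 of 22 alternatives and that of Spock1 in 9 of 21. With the stromal and muscle level as a term 386 genes were higher and 328 lower, and none of the 3 lists passed camera. The adjusted p was 0.0879 for the Wnt list (mean log2 fold change -0.31) and 0.119 for the epithelial-to-mesenchymal list (-0.40). It was 0.679 for the stromal list (-0.07), whose genes are part of that term.

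**Figure D4:**
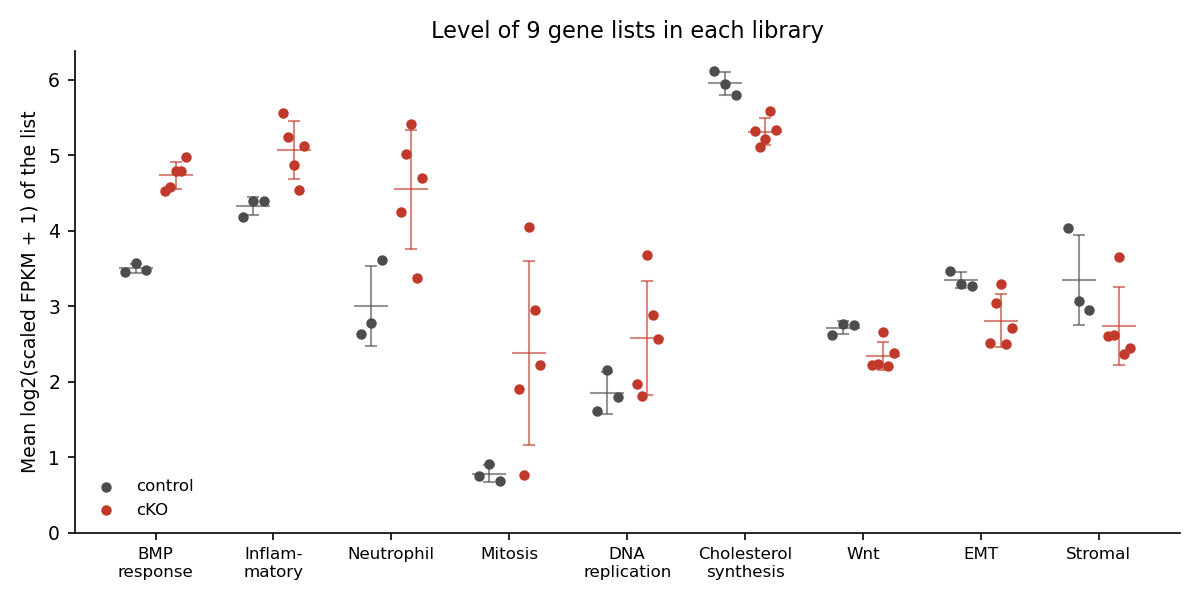
Mean log2(scaled FPKM + 1) of the 9 gene lists past the camera threshold in each library; points are 3 control (grey) and 5 cKO (red) libraries and bars show the mean and SD. Mitosis genes spread from 0.77 to 4.05 between cKO libraries, and the cholesterol list includes Fdft1, listed at 0 in cKO.

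Hormone-response lists did not pass. Among 24 tested estrogen-response genes 3 were higher and 1 lower, in both counts (camera adjusted p = 0.869). The list members Ltf and C3 were left out for their status, so the result does not cover them. Sprr2b rose from 1514 ± 982 to 5036 ± 1507 scaled FPKM and Sprr2g from 119 ± 89.0 to 425 ± 114, while Sprr2a1 fell from 127 ± 35.9 to 32.2 ± 18.5, and reads of these near-identical genes are uncertain. Mad2l1, the other higher member, lost its call in 11 of 22 alternatives, Sprr2b in 6, Sprr2a1 in 5 and Sprr2g in 3. Among 10 progesterone-response genes, Irg1, now Acod1, was higher (1.61 ± 0.24) and Fkbp5 lower (-0.73 ± 0.14), with 2 and 2 adjusted over the list alone (0.619). Among 5 tested glandular markers, Foxa2, a transcription factor required for uterine glands, was the 1 higher member in both counts, from 0.789 ± 0.301 to 5.25 ± 0.785 (log2 fold change 1.81 ± 0.15; list 0.970). Luminal markers Il15ra and Krt13 were higher among 11 in both counts (0.619). General epithelium markers had 3 of 21 higher in both counts (0.144), led by Spint1 at 131 ± 24.5 against 57.4 ± 11.2. The other higher members, Ocln and St14, each lost their call in 12 of 22 alternatives, and Spint1 in 0. Stratified epithelium markers did not pass (0.145), with Krt13, Krt15 and Krt17 higher among 9, and 4 higher and 1 lower adjusted over the list alone; Krt17 rose from 1.35 ± 1.03 to 17.9 ± 9.94. Krt13 lost its call in 3 of 22 alternatives and Krt15 in 4 of 21, as did Fkbp5 in 2 of 21.

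Of the 13 marker lists tested for a difference in mean level, 0 passed the exact permutation test after adjustment, with the lowest adjusted p at 0.232. Since the smallest p is 0.0179, a list could pass only if at least 5 of the 13 reached it, so this test could not show a shift of a few cell types. The unadjusted exact permutation p was 0.0357 for lymphocyte markers and 0.0536 for both neutrophil and stratified epithelium markers. The mean log2 differences were 0.69, 1.54 and 0.75. Macrophage and dendritic cell markers had 0 of 17 higher and 3 lower in both counts (camera adjusted p = 0.0831), among them Itgam, Laptm5 and Cd74, the last from 39.5 ± 11.4 to 18.2 ± 4.32 scaled FPKM. Lymphocyte markers had 0 of 5 called over all genes, 2 at an unadjusted p below 0.05 and 2 higher adjusted over the list alone (0.0582), and endothelial markers had Flt1 lower among 7 in both counts (0.360). The calls of Laptm5, Flt1 and Cd74 were lost in 9, 8 and 4 of 22 alternatives. Smooth muscle (0.0919), mesothelium (0.342) and red blood cell (0.275) lists had 0 members called by limma in both counts and 0 at an unadjusted p below 0.05, and the ciliated list had Tmem212 higher among 4 in both counts (0.360). Endometrial cancer driver genes and immediate early genes had 0 of 23 and 0 of 18 called by limma in both counts, with 6 and 2 at an unadjusted p below 0.05 (camera 0.762 and 0.862). Their most abundant members were Ctnnb1 at 434 ± 34.1 against 406 ± 56.9 and Ier3 at 814 ± 292 against 544 ± 154. Ppp2r1a, a cancer driver not called here, was called lower in 2 of 22 alternatives. Matrix metalloproteinase genes had Adamts1 and Adamts4 higher and Mmp14 lower among 14, and 3 higher and 2 lower adjusted over the list alone (0.869). The calls of Adamts4, Adamts1 and Mmp14 were lost in 14, 9 and 7 of 22 alternatives. The median, mean and camera direction differed in sign for the progesterone, complement, metalloproteinase, TGF-beta response, glandular, and glycolysis lists. Of the marker lists that did not pass camera, lymphocyte markers passed in 7 of 21 alternatives, smooth muscle in 4 of 22 and macrophage markers in 2 of 22. General and stratified epithelium, mesothelium and red blood cell lists each passed in 1. None of the 9 lists past camera passed with an estimated correlation. By fry, which asks whether the genes of a list move 1 way on balance, the BMP-response and cholesterol lists passed (adjusted p = 2.9e-05 and 0.0181). Fry was run on the full lists only, so these results include Id1 to Id4 and Fdft1, listed at 0 in cKO.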

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

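The tests of overlapping genes, mitosis genes and Itgam were chosen only after the results were seen. So were the names Ctsb, Entpd8, Noxa1, Itgb2, Tbc1d17, Ganc, Tmem87a, Hexdc, Synj2bp-cox16 and Cox16. The splits of the libraries were planned.

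In 8 of 138 sets of 5 cKO values, 1 library lay farther from the others than Dixon's ratio allows, where chance at 1 in 20 gives about 6.90. In cKO 5 these were Awat2 at 85.4 scaled FPKM (others 6.45 to 24.3), Defb1 at 360 (171 to 191), Vnn3 at 193 (31.7 to 59.1) and Smad1 at 21.0 (17.8 to 18.5). In cKO 4, Flt1 was at 2.96 (4.68 to 5.09) and the TGF-beta response list at a mean log2 level of 3.33 (3.86 to 4.01). In cKO 3, the stromal list was at 3.65 (2.37 to 2.63) and Ctsb at 452 scaled FPKM (784 to 899).

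Of the 56 splits of the 8 libraries into 3 and 5, only 1, the real one, gave as many as 823 higher genes (highest other 4) or 790 lower genes (3). The same held for 293 genes at least 2-fold higher (4) and 201 at least 2-fold lower (3). A chance split is therefore an unlikely source of these counts, but it is not excluded, since 56 splits allow no p below 0.0179. Every other split also mixes control and cKO libraries within a group, which widens the spread and favours low counts. For gene lists past camera chance can account for the number: 33 of the 56 splits gave 9 or more, and the highest other gave 15.

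The 8 genes listed at 0 in all 5 cKO libraries and at 1 or more in every control each overlap another expressed gene, against 8.42% of other tested genes (Fisher's exact p = 2.6e-09), an overlap that prompted the test. Of all 46 tested genes at 0 in some library and at 5 or more in another 40 overlap (87.0%, Fisher's exact p = 3.66e-37), and of the 40 outside the first set 34 do (85.0%, Fisher's exact p = 4.99e-31). Fdft1 (chromosome 14, 63145151 to 63179578) meets Ctsb (63122462 to 63145923), which was higher in cKO by 1.14 ± 0.27 on the log2 scale. That call was lost in 8 of 22 alternatives. Tmem87a, the partner of Ganc, was also higher, by 0.45 (limma adjusted p = 0.019), and Noxa1, the partner of Entpd8, was lower. The most abundant partners of Il4i1, Acat3, Nox1, Hexdc and Synj2bp-cox16 were not called. Zeros thus went with overlap, and assignment of fragments to the overlapping neighbour may take part. However, Fdft1 meets Ctsb only at an end, as Il4i1 (chromosome 7, 44836288 to 44840809) meets Tbc1d17 (44840776 to 44849079). Assignment of the shared stretch would leave fragments from the rest of these 2 genes, and Tbc1d17 was at 11.8 scaled FPKM in both groups. Acat3, Entpd8, Ganc, Hexdc and Nox1 also meet their most abundant partners only at an end, while Synj2bp-cox16 spans the whole of Cox16. Overlap does not by itself say why 8 genes were at 0 in all cKO libraries and only 1 in all controls. A failed estimate where genes overlap and a loss of these transcripts in cKO both stay open, and without reads they cannot be separated.

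The mitosis rise differs between cKO libraries. That 1 library carries it is argued against, since without cKO 3 the mean log2 fold change was 1.22 and the list still passed camera. Variation between libraries unrelated to genotype, biological or technical, may account for it: the exact permutation p of the mean level was 0.0714, above 0.05, and cKO 2 lay in the control range. Within the main title series, however, cKO 3, 4 and 5 all lay above the controls (mean log2 fold change 2.31). The lowest cKO libraries, cKO 1 and cKO 2, belong to the other series, which the permutation does not take into account. A difference in proliferation with genotype stays open.

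Itgam fell from 51.2 ± 10.5 to 6.28 ± 1.71 scaled FPKM, lower in 5 of 5 cKO libraries. Itgb2, its usual partner subunit, was at 2.14 ± 0.783 in control and 4.45 ± 2.51 in cKO, with overlapping groups and no call (limma adjusted p = 0.28). Fewer leukocytes overall as the whole cause is argued against: the other 31 tested leukocyte markers had a median log2 fold change of 0.49, with an interquartile range of 1.47, against -2.86 for Itgam. The 16 other macrophage and dendritic cell markers had a median of -0.37 with an interquartile range of 0.628, and the lowest was Cd74 at -1.06, so fewer of these cells may add to the fall but are argued against as its whole cause. Assignment to an overlapping gene is also argued against, since 0 expressed genes overlap Itgam. A lower Itgam level in the epithelial cells themselves is a hypothesis that these bulk libraries cannot separate from a change within 1 leukocyte type.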

How the results depend on the processing

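All alternatives were planned except leaving out genes listed at 0, chosen after seeing the data, which gave 828 higher and 791 lower genes. Smad2 stayed lower and past the threshold in all 22 alternatives (leave-one-out log2 fold change -0.67 to -0.58). The permutation test of marker lists could hardly pass with fewer libraries, so its alternatives say nothing about stability. No called gene was called in the opposite direction under any alternative. For 100 single genes, most chosen by the rule for named genes, 1883 results kept direction and side of the threshold, 273 lost and 10 gained a call. Many of these genes were chosen for large or clear changes, so they do not stand for all calls. Of all 1613 calls, 25.7% were kept without control 3, 26.2% without control 2 and 42.5% with the stromal and muscle term. Without the other title series 61.7% were kept, and the highest share was 99.9%, with genes of other status kept. For lists the numbers were 604, 29 and 26. The causes of the changes below were not tested, except that leaving out a control leaves 2 and that a stricter filter tests fewer genes.

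TPM gave 512 higher, 1616 lower and 433 at least 2-fold lower genes; FPKM 5 gave 128 at least 2-fold lower; array weights 1793, 1733 and 444 at least 2-fold higher; the stromal and muscle term 386 and 328. Leaving out 1 library gave 238 to 928 higher, 176 to 887 lower, 157 to 338 and 93 to 223 at least 2-fold higher and lower, and 7 to 14 lists; the estimated correlation gave 0 lists. Smad3, not called, turned to -0.12 with TPM, -0.019 with array weights, -0.18 without the other title series and -0.19 with it as a term, and ranged from -0.045 to 0.20 leaving out 1 library.

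The camera direction of lists not past the threshold with all 8 libraries turned as follows (mean log2 fold change). Camera compares a list with the other tested genes, so the sign of the mean need not be the direction turned to. The TGF-beta family, TGF-beta response, progesterone, complement, metalloproteinase and smooth muscle lists turned from lower to higher. The estrogen, glycolysis, cancer driver, general epithelium, glandular, interferon and immediate early lists turned from higher to lower. With TPM: TGF-beta family -0.21, TGF-beta response -0.13, progesterone -0.11, metalloproteinases -0.20. Unscaled: metalloproteinases -0.057. Quantile: estrogen -0.068, glycolysis -0.24, general epithelium -0.070. Pseudocount 0.1: glandular 0.21. No filter: complement 0.018, metalloproteinases -0.0034. FPKM 5: progesterone 0.25, estrogen 0.098, cancer drivers 0.037, metalloproteinases 0.25, glandular -0.50. Without the other title series: estrogen -0.028, immediate early -0.26; as a term: estrogen -0.033, glycolysis -0.17, immediate early -0.27. Stromal and muscle term: TGF-beta family 0.036, interferon 0.024, metalloproteinases 0.21, smooth muscle 0.11. Leaving out 1 library: estrogen -0.034 to 0.28, immediate early -0.21 to 0.37, glandular -0.12 to 0.19, TGF-beta response -0.077 to 0.13, metalloproteinases -0.12 to 0.20. Of genes not called, Ctnnb1 turned to -0.11 with TPM and -0.18 with quantile normalization, and Btg2 (-0.33 to 0.028) and Pgr (-0.31 to 0.019) without control 1.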

Other observations

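The test of the BMP-response list without the Id genes was chosen only after the result was seen, as were the Sprr2 genes named here outside the rule; the test of genes near Pgr was planned.

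The Sprr2 genes, which encode small proline-rich proteins of the epithelial surface and lie together on chromosome 3, moved in different directions. Sprr2a1, Sprr2a2 and Sprr2a3 were lower in cKO by similar amounts, with log2 fold changes of -2.11 ± 0.46, -2.02 ± 0.44 and -2.14 ± 0.46 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0192, 0.0192 and 0.019), and all 5 cKO libraries lay below the controls. Sprr2b and Sprr2g were higher, at 1.90 ± 0.44 and 2.03 ± 0.41 (adjusted p = 0.0234 and 0.0156). Sprr2f, the most abundant, did not pass at 10035 ± 3334 against 8509 ± 3528 scaled FPKM. The calls were lost in 3 to 6 of 22 alternatives, and because fragments of these near-identical genes can be shared, the division between members is uncertain.

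A hypothesis that the rise of Id1 to Id4 reflects a rise of the whole BMP-response list was tested on the 6 other tested members. Their mean log2 fold change was -0.20, with 1 higher and 2 lower, and their median of -0.16 lay below the smallest Id value of 2.48 by more than their interquartile range of 1.09. The higher member was Bambi, at 0.72 ± 0.18. The other members as a set therefore did not rise with the Id genes, and BMP signalling itself was not measured.

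A segment of chromosome 9 carried along with the Pgr-cre allele might hold called genes more often than the rest of the genome. Within 10 Mb of Pgr, 4 of 37 tested genes were called (10.8% against 14.3% elsewhere; odds ratio 0.728, 95% interval 0.187 to 2.05, Fisher's exact p = 0.813). With so few genes an effect of the segment cannot be told apart from none.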
